A study of Mus musculus with 15 samples.

How the data were processed

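RNA was measured in 15 libraries of mouse intestinal epithelial cells, sorted as Epcam-positive, CD45-negative and CD31-negative cells with a high or a low signal of a green fluorescent Lrig1 reporter, from normal colonic epithelium or from colonic tumors of Apc-min mice, per the labels' protocols. The libraries were made with a stranded total RNA kit for very small inputs with removal of ribosomal RNA fragments, and were sequenced from both ends, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, Subread and featureCounts and the mm10 genome build. The deposited values are raw read counts per gene, made with featureCounts 1.5.3 on exons of mm10 RefSeq genes in the reverse strand setting, per the file headers. The command in the header names no option for counting fragments, so each end of a pair was counted as a read. No option for multi-mapping or overlapping reads is named there either, so near-identical genes such as the defensins can lose reads.

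The table holds 27179 genes. A symbol was found for 25262 gene identifiers in the RefSeq table and for 31 more in GENCODE M21, and 1886 stayed without a symbol. The genes without a symbol took 3.96% to 7.80% of the counts of a library, in the 14 libraries with reads. The groups came from the sample titles, which also give each library a running number (S01 to S15). The labels name no animal, so p-values measure the spread between these libraries only, which can be technical in part.

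The fixed plan was to fit all 15 libraries together. The library S15, labelled tumor Lrig1-low, turned out to hold 357 counts in 47 genes, against 9508505 to 17296536 counts in the others, and was left out. This departs from the plan, and the counts of genes with S15 included are given beside the results they change. The tests were run in edgeR 4.0.16 under R 4.3.3, with TMM scaling, the filterByExpr filter (13883 genes tested), a coefficient per group, the quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested, with calls at an adjusted p under 0.05. The standard error of a log2 fold change was computed as its absolute value divided by the square root of F. CPM values are counts scaled to the library size with the TMM factors (edgeR's cpm).

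Gene lists were fixed before the data were examined, with markers of other cell types and technical lists among them, and 33 lists with at least 5 tested members were tested in limma 3.58.1 with camera at a preset correlation of 0.01. The same lists were tested with an estimated correlation and with the rotation test fry. The named genes were chosen by a rule fixed at the same time. The rule takes Lrig1 and, per comparison and direction, the 8 genes with the largest absolute log2 fold change among those past the threshold with a mean of at least 10 CPM and no overlap between the libraries of the groups. It also takes up to 3 members per direction of each described list by smallest adjusted p, or, where none passed, up to 2 members with the highest mean. For the interaction it takes genes past the threshold by smallest adjusted p, and there were none. Apc, the sort markers Epcam, Ptprc and Pecam1, the sex-linked genes, Camk2d and Fabp6 are named outside this rule, the last 2 after their values were seen. Predicted, mitochondrial, ribosomal protein, immunoglobulin and T cell receptor genes were passed over for the 8. Single values such as Lrig1 were compared with exact two-sided permutation tests. Overlaps of calls were tested with Fisher's exact test between comparisons that share no library.

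Each result was recomputed with DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter, at least 1 CPM in at least 4 libraries, only the groups compared, limma-voom with sample weights, the runs of consecutive library numbers as a block, and leaving out each library in turn. These were fixed at the start, and further library sets were chosen after seeing the data. The Lrig1 gene and the stem cell list level of 4 libraries (S07, S08, S09 and S10) went against their labels. The Wnt target level of S10 did not, at 3.72 (mean log2(CPM + 1)) against 3.15 to 3.51 in the other normal Lrig1-high libraries. The fits were repeated on the 10 libraries without those 4, on 9 libraries without S12 as well, and on 13 libraries without S12 alone. Those 4 libraries were picked by their levels of Lrig1, stem cell genes and Wnt target genes. The lists that raised the doubt also held DNA replication, mitosis, Paneth, tuft cell and histone genes. The fit on 10 libraries is therefore not independent evidence for any difference that goes with those genes, its p-values are too small, and it is reported only as an alternative. No library was moved to another group. As a gauge, 100 sets of 1 library left out per group were fitted, the set of those 4 included.

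The tests were checked on simulated counts with the means, library sizes and spread of the 13883 genes. The changed genes were drawn only from genes above a floor of mean CPM, so the shares called do not cover weaker genes. In the comparison of tumor with normal Lrig1-low cells, the test called 9 of 50 genes changed 2-fold, 28 of 50 changed 4-fold, 40 of 50 changed 8-fold and 50 of 50 changed 16-fold, and 4 unchanged genes. In the comparison of Lrig1-high with Lrig1-low normal cells, it called 6 of 50, 29 of 50, 44 of 50 and 46 of 50 at the same folds, and 4 unchanged genes. It called 2, 32, 37 and 46 of 50 and 6 unchanged genes in the tumor sort. In tumor against normal Lrig1-high cells it called 6, 31, 42 and 47 of 50 and 4 unchanged genes. For the interaction it called 2, 11, 27 and 34 of 50 and 4 unchanged genes. Camera missed a 2-fold shift of the Wnt target list in the normal sort (adjusted p = 0.0609) and the interaction (adjusted p = 0.0838). It called the shift in the other comparisons. Genes were simulated independently of each other, so false calls of camera under correlated genes were not tested.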

Results

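Gene expression was measured by RNA sequencing in sorted epithelial cells of mice that carry the Apc-min mutation, which gives intestinal tumors, and a fluorescent reporter of Lrig1, a membrane protein of intestinal stem and progenitor cells that restrains ErbB receptors. Cells were sorted into Lrig1-high and Lrig1-low fractions from tissue labelled normal colonic epithelium and colonic tumors. The median of small intestine markers was 69.8 to 382.4 CPM in the 14 libraries with reads, against 1.44 CPM or less for colon markers. The colon is therefore named here by the labels only. The table holds 4 normal Lrig1-low, 4 normal Lrig1-high, 4 tumor Lrig1-low and 3 tumor Lrig1-high libraries. In 14 of them the total was 9508505 to 17296536 counts. The tumor Lrig1-low library S15 held 357 counts and was not compared, which left 3 libraries in that group. Mitochondrial ribosomal RNA took 12.9% to 42.8% of the counts of the 14 libraries, with the highest share in the tumor Lrig1-high library S12, which also had the fewest genes with a count, 11995.

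Lrig1 (gene 16206, mm10 chromosome 6, 94604529 to 94700145) was compared first, because it checks the sort labels. In normal epithelium it was at 59.03 ± 18.03 CPM in libraries labelled Lrig1-low and 111.7 ± 50.9 CPM in libraries labelled Lrig1-high (SD, n = 4 each), and an exact two-sided permutation test on log2 CPM gave p = 0.171. In tumors it was at 79.3 ± 54.3 CPM in libraries labelled Lrig1-low and 92.1 ± 49.3 CPM in libraries labelled Lrig1-high (SD, n = 3 each), with an exact permutation p = 0.5, where 0.1 is the smallest that 3 against 3 can give. In edgeR the log2 fold change of Lrig1-high over Lrig1-low was 0.92 ± 0.47 in normal epithelium (SE, adjusted p = 1) and 0.22 ± 0.54 in tumors (adjusted p = 0.933), and limma-voom with sample weights gave 1.26, past its threshold, and 0.77, not past it. Between tumor and normal tissue Lrig1 differed by -0.28 ± 0.51 in Lrig1-high cells and by 0.43 ± 0.50 in Lrig1-low cells (adjusted p = 0.852), neither past the threshold, and the interaction was -0.70 ± 0.71 (adjusted p = 0.796). Lrig1 went against the label in 4 libraries. The library labelled normal Lrig1-high S10 had 36.4 CPM, below each library labelled normal Lrig1-low, and the library labelled normal Lrig1-low S09 had 85.5 CPM, above the other 3 of its label at 45.3 to 54.0 CPM. The library labelled tumor Lrig1-low S07 had 141.7 CPM against 53.2 and 43.0 CPM in the others of its label, and the library labelled tumor Lrig1-high S08 had 55.7 CPM against 148.2 and 72.6 CPM. S09 stayed below the normal Lrig1-high libraries other than S10, at 126.2 to 145.9 CPM. S12, labelled tumor Lrig1-high and at 72.6 CPM, lay below S09 but was not counted among the 4. Every direction below rests on these labels as deposited. Of the sort markers, Epcam, the epithelial marker used for the sort, was at 604.7 to 1509 CPM, and Pecam1, which encodes CD31, was at 1.85 CPM or less in all 14 libraries. Ptprc, which encodes CD45, was at 46.1 CPM in S08 and at 11.2 CPM or less in the others. The level of the whole leukocyte list in S08, 0.324 in mean log2(CPM + 1), lay within the 0.098 to 0.465 of the others. Apc was at 215.4 to 310.9 CPM.

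**Figure D1:**
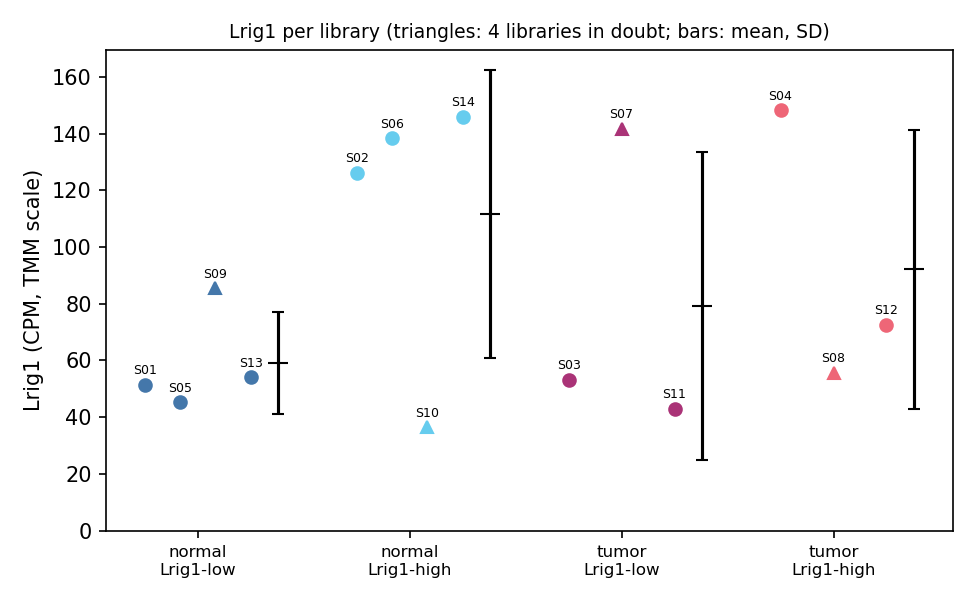
Lrig1 in each of the 14 libraries in CPM on the TMM scale, by labelled group, with the group mean and SD as a bar and the libraries S07 to S10 as triangles. The library labelled normal Lrig1-high S10 lies at 36.4 CPM and the library labelled tumor Lrig1-low S07 at 141.7 CPM.

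Tumor and normal cells were compared within the Lrig1-low fraction to ask what differs between transformed and normal cells with little Lrig1. Fn1, which encodes the matrix protein fibronectin (gene 14268, chromosome 1, 71585523 to 71653171), was at 126.9 CPM in the libraries labelled tumor and 0.57 CPM in those labelled normal, a log2 fold change of 7.78 ± 1.41 (SE, n = 3 and 4, adjusted p = 0.0359). Thbs1, which encodes the matrix glycoprotein thrombospondin-1, differed by 5.66 ± 0.91 (adjusted p = 0.0188), and Flna, which encodes the actin crosslinker filamin A, by 3.41 ± 0.38 (adjusted p = 0.0058). Cd44, a Wnt target that encodes a receptor of hyaluronan, differed by 3.07 ± 0.44 (adjusted p = 0.0106). In all, 43 genes were higher and 3 lower in edgeR at an adjusted p under 0.05. The number of genes with at least 10 counts was higher in the tumor libraries too, with a mean of 13300 against 12480. Its exact two-sided permutation p was 0.0286, the smallest that 4 against 3 can give, with an adjusted p of 0.495 over the comparisons of library measures.

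The other genes with the largest increase by the fixed rule were Arhgef17, also a member of the YAP and TAZ target list (log2 fold change 4.96), Limch1 (4.40), Sting1 (4.25), Ccdc3 (4.05), Sh3pxd2b (3.92) and Cgnl1 (3.64). Sting1 encodes a sensor protein of the response to cytosolic DNA, and Sh3pxd2b an adaptor protein of podosomes. Each had higher CPM in all 3 tumor than in all 4 normal libraries of this fraction. The 3 genes that were lower were Me2, a mitochondrial malic enzyme (-1.34 ± 0.25, adjusted p = 0.0412), Thra, the thyroid hormone receptor alpha (-1.05 ± 0.20, adjusted p = 0.0416), and Gata4, a transcription factor of the proximal intestine (-0.94 ± 0.17, adjusted p = 0.0359). The median CPM of markers of the small intestine was lower in the tumor libraries of this fraction as well, at 193.2, 69.8 and 89.8 CPM against 200.7 to 243.6 CPM in the normal libraries. Without the defensins and Lyz1 the tumor library S03 was at 213.3 CPM, above the normal library S09 at 208.4 CPM.

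**Figure D2:**
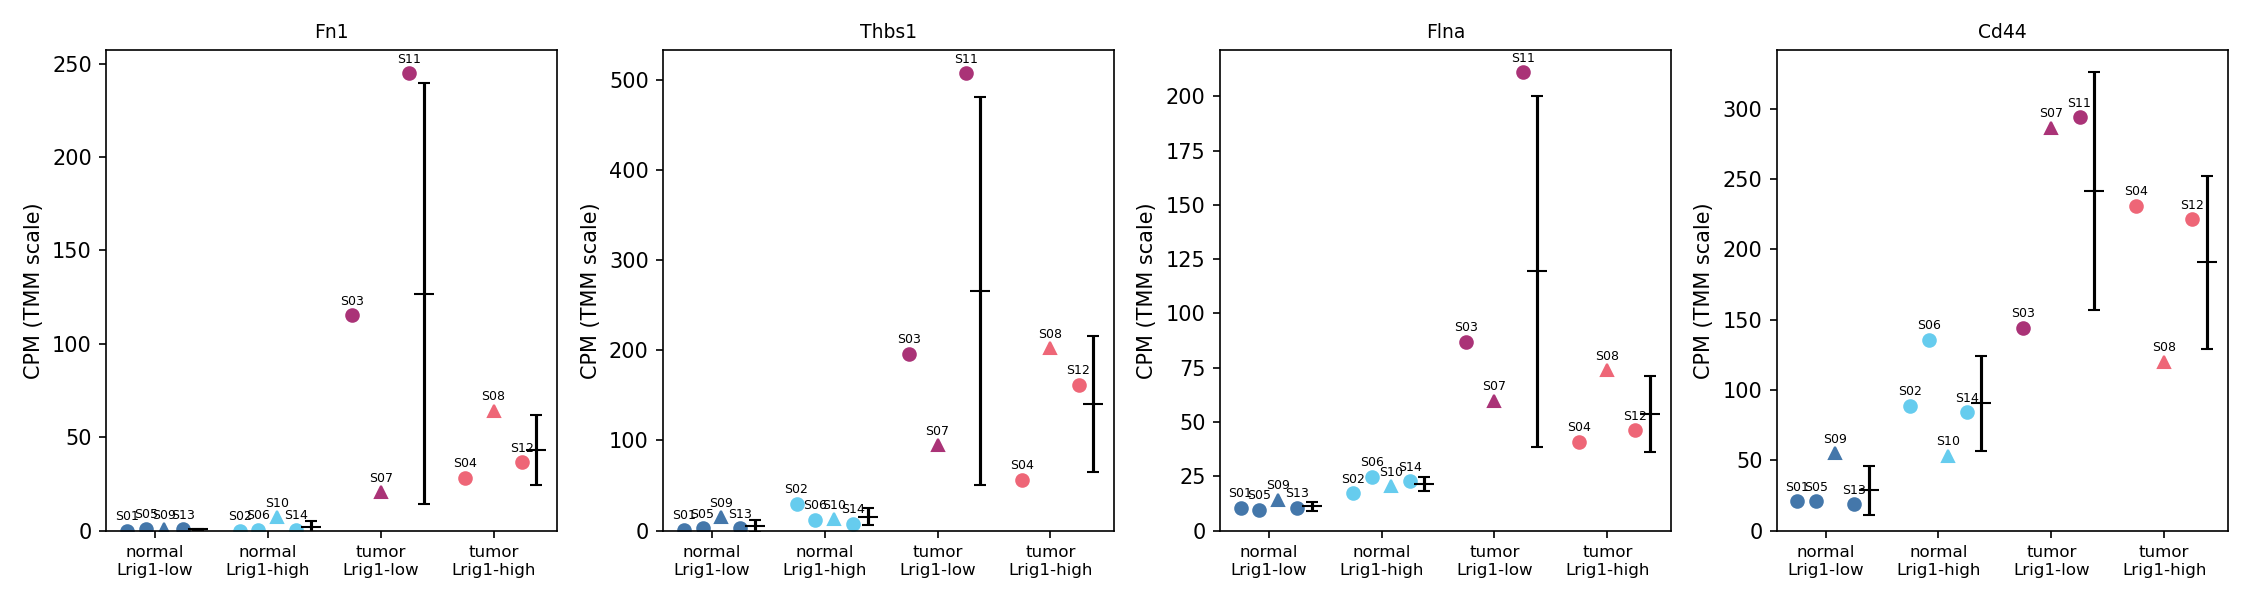
CPM on the TMM scale of Fn1, Thbs1, Flna and Cd44 in each of the 14 libraries, by labelled group, with the group mean and SD as a bar and the libraries S07 to S10 as triangles. In the Lrig1-low fraction the tumor libraries lie above the normal libraries for each of these genes.

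Among the lists, the Wnt and beta-catenin targets had 22 of 22 members with a positive fold and a median log2 fold change of 3.30. Cd44 and Sp5 (3.41 ± 0.60, adjusted p = 0.0337) passed over all genes tested, and 18 members passed when adjusted over the list alone. Camera gave an adjusted p = 4.03e-22 with the preset correlation and 0.0843 with an estimated correlation. The basement membrane list had 1 of 23 members higher, Lamb2, which encodes a laminin chain (3.41 ± 0.63, adjusted p = 0.0363), with 10 adjusted over the list alone, and an adjusted p = 3.17e-06 by camera but 0.221 with an estimated correlation. The integrin and focal adhesion list had 1 of 41 higher, Flna, with 9 adjusted over the list alone (camera adjusted p = 0.00137, and 0.159 with an estimated correlation). The matrix remodelling list had 1 of 19 higher, Mmp14, a membrane-bound metalloproteinase (1.83 ± 0.35, adjusted p = 0.0426), with 6 adjusted over the list alone (camera adjusted p = 1.03e-06, and 0.159 with an estimated correlation).

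Phlda1 in the ErbB and MAPK feedback list (2.95 ± 0.37, adjusted p = 0.00907), Tgfbr2, a receptor of TGF-beta, in the BMP and TGF-beta list (2.29 ± 0.35, adjusted p = 0.0156), and Icam1, an adhesion molecule of inflammation (5.08 ± 0.93, adjusted p = 0.0359), were each the 1 member of their list that passed over all genes. Adjusted over the list alone, 6 members were higher and 3 lower in the ErbB list, 4 and 1 in the BMP list, 4 and 0 in the epithelial inflammation list, and 6 and 1 in the YAP and TAZ target list. Their camera adjusted p values were 0.00221, 0.000596, 0.00235 and 0.00418, and with an estimated correlation the adjusted p values were 0.344, 0.337, 0.108 and 0.42. The intestinal stem cell list (median 1.66) and the fetal and regenerative list (median 3.97) had no member past the threshold over all genes and 7 of 20 and 10 of 16 adjusted over the list alone. Their camera adjusted p values were 5.41e-11 and 4.93e-07, and both were 0.275 with an estimated correlation. The nuclear genes of oxidative phosphorylation had 37 of 37 members with a negative fold and a median of -0.59, no member past the threshold over all genes, 7 adjusted over the list alone, and camera adjusted p = 6.16e-14, or adjusted p = 0.201 with an estimated correlation. The genes of the mitochondrial genome moved the same way, with a negative fold in 14 of 15, a median of -0.56 and a camera adjusted p = 0.00735, or adjusted p = 0.603 with an estimated correlation. Camera called 13 lists up and 6 down in all. By fry, which asks whether a list moves on balance, 6 lists passed, and with an estimated correlation 0 did. Markers of endothelial cells moved with these lists, with a median log2 fold change of 1.30 over 9 members (camera adjusted p = 0.0157, and adjusted p = 0.375 with an estimated correlation) and a level of 1.60 (mean log2(CPM + 1)) in S11, and Fn1 is also a marker of fibroblasts.

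All 43 genes were also called by DESeq2, which called 545 higher and 161 lower, and by limma-voom with sample weights, which called 1060 and 329. With the near-empty library S15, as first planned, 90 were higher and 2 lower, with 39 of the 43 among the first and 0 of the 3 lower genes among the second. The count rests on single libraries, here given by their numbers. It was 0 higher and 0 lower without S01, and 4 higher without S05, 3 without S13, 3 without S11 and 28 without S04, with 0 lower in each, while it was 67 higher and 57 lower without S03, 150 and 1 without S07, 119 and 8 without S09, 202 and 38 without S10, and 226 and 59 without S12. Without S02, S06 or S14 it was 30 to 32 higher and 0 or 1 lower. Each named gene lost its call without S01, and each but Flna and Phlda1 also without S05, S11 and S13, and the highest adjusted p of a named gene over all settings lay between 0.0545 and 0.259. Without the 4 libraries whose Lrig1 went against the label, chosen after seeing the data, 432 genes were higher and 20 lower. All 43 were among the first and 2 of the 3 lower genes among the second. In that set each tumor group holds 2 libraries. Leaving out S12 as well gave 1523 and 584, S04 1432 and 498, S01 71 and 0, S05 74 and 2, S13 100 and 0, and S02, S06 or S14 234 to 244 higher and 5 or 6 lower. Without S11 the count was 68 and 0 and without S03 582 and 411, where 1 tumor Lrig1-low library is left and is assumed to vary like the other groups.

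Lrig1-high and Lrig1-low cells were compared in normal epithelium to ask what marks cells with much Lrig1. Lists of crypt cells had positive folds in the libraries labelled Lrig1-high. The intestinal stem cell list had a positive fold in 20 of 20 members with a median of 1.64, 0 past the threshold over all genes and 10 adjusted over the list alone, and its members with the highest mean, Olfm4 and Slc12a2, had folds of 3.17 ± 1.65 and 1.70 ± 0.84. Its camera adjusted p was 1.99e-23, and 0.243 with an estimated correlation. The Paneth and deep crypt secretory list had a median of 1.74 (camera adjusted p = 2.29e-08, and 0.528 with an estimated correlation), the DNA replication list 1.11 (camera adjusted p = 3.83e-12, and adjusted p = 0.607 with an estimated correlation) and the mitosis list 0.87 (camera adjusted p = 9.69e-08, and adjusted p = 0.607 with an estimated correlation). The technical lists of histone and of ribosomal protein genes moved with them, with medians of 1.11 and 0.23 (camera adjusted p = 1.01e-09 and 6.92e-07, and adjusted p = 0.607 and 0.694 with an estimated correlation). The colonocyte list of absorptive cells had a median of -0.73 (camera adjusted p = 8.58e-08, and adjusted p = 0.558 with an estimated correlation) and the tuft cell list -0.99 (camera adjusted p = 9.24e-05, and adjusted p = 0.694 with an estimated correlation). No gene passed in edgeR, with 0 higher and 0 lower, 499 genes at an unadjusted p under 0.05 against 694 that chance gives, and 1 higher and 0 lower in DESeq2. No list passed with an estimated correlation or by fry in this comparison.

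The count in normal epithelium depended on the tool and the libraries. Limma-voom with sample weights, which weights libraries by their spread and was fixed at the start, called 2057 genes higher and 2112 lower on the 14 libraries, and its weights were 0.348 for S10 and 0.691 for S09 against 1.84 to 3.33 for the other normal libraries. Without the 4 libraries whose Lrig1 went against the label, chosen after seeing the data, 474 genes were higher and 322 lower, of which limma-voom on 14 libraries also called 464 and 297. Because the 4 were picked by the genes that mark the sort, these counts are not independent evidence. The weights of limma-voom come from the same values and labels and were lowest for S09 and S10 among the normal libraries. Its overlap with the fit on 10 libraries is therefore partly built in. In that set of 10 libraries 19 of 20 stem cell genes were higher, such as Smoc2 (2.21 ± 0.23, adjusted p = 0.00612) and Ephb3 (3.05 ± 0.36, adjusted p = 0.00612). Lyz1, a lysozyme of Paneth cells, was higher by 5.98 ± 0.94 (adjusted p = 0.0103), and Sst, which encodes somatostatin, lower by a log2 fold change of -5.45 ± 0.81 (adjusted p = 0.00934). Leaving out 1 more library moved the count from 82 higher without S01 to 1856 without S04, and from 12 lower without S06 to 1622 without S12. Without S04 or S12 the tumor Lrig1-high group holds 1 library and adds nothing to the estimate of the spread.

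The sort was compared in tumors for the same question. The basement membrane list had a median log2 fold change of -1.19 in libraries labelled Lrig1-high (camera adjusted p = 0.012, and 0.844 with an estimated correlation), with Agrn at -0.33 ± 0.31 and Lama5 at -1.02 ± 0.91, its members with the highest mean. Markers of endothelial cells moved with it, with a negative fold in 8 of 9, a median of -1.51 and a camera adjusted p = 0.0278, or adjusted p = 0.844 with an estimated correlation. The mitochondrial genes had a median of 1.40 (camera adjusted p = 1.71e-06, and adjusted p = 0.844 with an estimated correlation), and S12, with 6.69% of its counts in mitochondrial genes other than ribosomal RNA, is in the Lrig1-high group. The stem cell list did not pass on the 14 libraries, with a median of -0.04 and Olfm4 at 0.48 ± 1.76. No gene passed in edgeR, with 0 higher and 0 lower, 1042 genes at an unadjusted p under 0.05 against 694 by chance, and 6 higher and 16 lower in DESeq2. Without the library labelled tumor Lrig1-high S04, 41 genes were higher and 324 lower. Without the 4 libraries in doubt, 45 genes were higher and 3 lower, among them the histone gene H3c2 (3.15 ± 0.47, uncertain because histone genes have near-identical copies) and the mitosis gene Ube2c (2.62 ± 0.30). The stem cell list then had a median of 0.83 and 3 of 20 members higher, Slc12a2 (2.38 ± 0.36), Cdo1 (2.59 ± 0.40) and Smoc2 (1.82 ± 0.28), each at an adjusted p = 0.0464, with a camera adjusted p = 1.01e-05, or adjusted p = 0.181 with an estimated correlation, in a set that was picked in part by these genes. With S01, S02, S06, S13 or S14 also left out the counts of 45 and 3 were 0 and 0. Leaving out S04 as well gave 2825 and 4437, but this sets S12 alone, the library with the most mitochondrial RNA, against S03 and S11, with the spread taken from the other groups. Limma-voom called 0 in both sets of libraries.

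Tumor and normal cells were compared within the Lrig1-high fraction as well. The epithelial inflammation list was the 1 list that passed by every list test on the 14 libraries: 16 of 17 members had a positive fold, the median log2 fold change was 1.31, 0 members passed over all genes and 5 adjusted over the list alone. Its adjusted p was 9.4e-07 by camera, 0.00994 with an estimated correlation and 0.00343 by fry, and its members with the highest mean were Reg3b (1.31 ± 0.80) and Pigr (-1.04 ± 0.54). The call of this list was lost with an estimated correlation without the 4 libraries in doubt (adjusted p = 0.116), where the camera adjusted p was 5.5e-05 and that by fry 0.0274. The fetal and regenerative list had a median of 1.98 (camera adjusted p = 9.71e-07, and 0.48 with an estimated correlation), with Clu at 2.10 ± 1.64, and the Wnt target list 0.96 (camera adjusted p = 0.000153, and adjusted p = 0.793 with an estimated correlation). The genes of the mitochondrial genome moved with these lists, with a positive fold in 14 of 15, a median of 1.06 and a camera adjusted p = 0.00194, or adjusted p = 0.857 with an estimated correlation, and S12, with 42.8% mitochondrial ribosomal RNA, is in the tumor group. Of 5 fibroblast markers, 2 had a positive fold, Fn1 (4.43 ± 1.20) and Acta2 (4.16 ± 1.37), and both passed adjusted over the list alone. None passed over all genes. The list median was -1.55 (camera adjusted p = 0.332, and adjusted p = 0.827 with an estimated correlation). Lists of other epithelial cell types went both ways. Tuft cells had a positive fold in 22 of 22 members with a median of 1.38 (camera adjusted p = 0.0307, and adjusted p = 0.939 with an estimated correlation) and goblet cells a median of 0.66 (camera adjusted p = 0.00194, and adjusted p = 0.827 with an estimated correlation). The enteroendocrine list had a median of -0.71 (camera adjusted p = 0.00174, and adjusted p = 0.827 with an estimated correlation). The Paneth and deep crypt secretory list had a median of -0.80 (camera adjusted p = 0.969). With the 4 libraries in doubt left out the tuft cell median turned to -0.31, with 8 of 21 members positive (camera adjusted p = 0.773), and the goblet cell median was 0.53 (camera adjusted p = 0.0507). S08 had the highest level of the 14 libraries in both the tuft cell list (5.34, mean log2(CPM + 1)) and the inflammation list (3.87). No gene passed in edgeR, with 0 higher and 0 lower, 1559 genes at an unadjusted p under 0.05 against 694 by chance, and 74 higher and 40 lower in DESeq2. Total counts differed between these groups at an exact two-sided permutation p = 0.0286, the smallest that 4 against 3 can give, and an adjusted p of 0.495 over the 52 comparisons of library measures. Limma-voom called 0. Without S04, 263 genes were higher and 544 lower. Without the 4 libraries in doubt, 12 genes were higher and 0 lower. The largest folds by the fixed rule were those of Muc6 (12.41 ± 1.59), Wfdc18 (12.26 ± 1.25), Robo1 (8.36 ± 1.15), Ctse (7.15 ± 0.71) and Lrg1 (7.09 ± 0.93). Wfdc18 and Robo1 had 1 and 3 counts in the normal group, so the sizes of their folds are uncertain. Clu, a marker of regenerating epithelium (7.05 ± 0.94), and Notum, a Wnt inhibitor (6.89 ± 0.79), came next. With S01, S02, S05, S06 or S14 also left out the counts of 12 and 0 were 0 and 0. Leaving out S04 as well gave 3178 and 4393, but this sets S12 alone against the normal group, with the spread taken from the other groups.

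Whether the sort difference itself differed between tumor and normal tissue was tested as an interaction. No gene passed in edgeR, with 0 and 0 calls, 999 genes at an unadjusted p under 0.05 against 694 by chance, and 1 higher and 4 lower in DESeq2. Of 33 lists, 8 passed upward and 7 downward by camera, and 0 with an estimated correlation and 0 by fry. Without S04 there were 7 genes higher and 150 lower. The overlap of sort calls between normal and tumor tissue was 0 with no calls to share, and the log2 folds had a Pearson r of -0.10 and a Spearman rho of -0.086 across genes, which are not independent replicates. The tissue folds of both fractions had r = 0.341 and rho = 0.237. Without the 4 libraries in doubt, 44 of the 45 genes higher in the tumor sort were among the 474 of the normal sort (1.53 expected for independent lists, Fisher's exact p = 1.27e-64). In both directions 46 sort calls were shared, and 0 with S01, S02, S06, S13 or S14 left out as well. With S04 left out 1191 were shared, where S12 is the 1 tumor Lrig1-high library. That overlap is partly built in, since libraries were left out in both tissues by the genes that mark the sort.

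**Figure D3:**
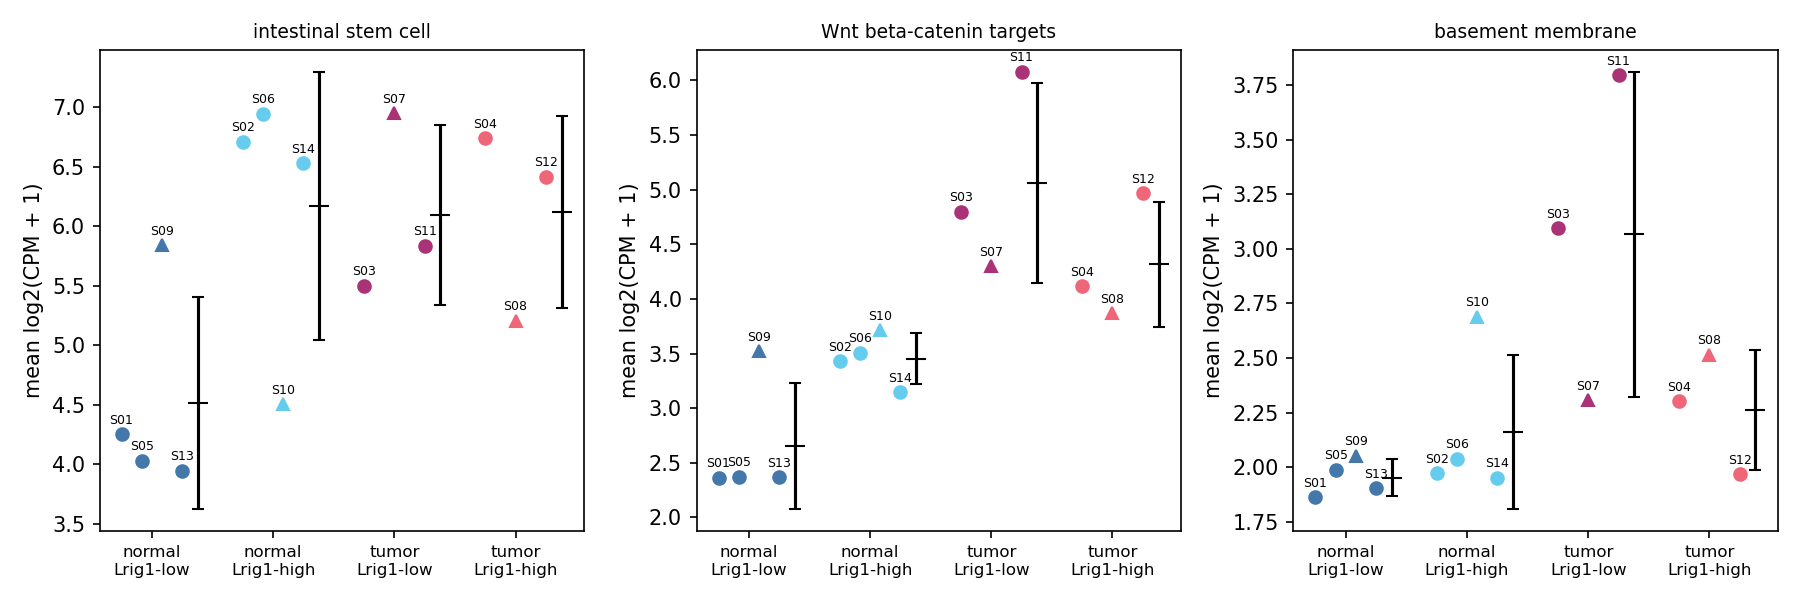
Mean log2(CPM + 1) over the members of the intestinal stem cell, Wnt target and basement membrane lists in each of the 14 libraries, by labelled group, with the group mean and SD as a bar and the libraries S07 to S10 as triangles. In the stem cell list S10 lies at 4.50 and S09 at 5.84, and in the Wnt target list the highest library is S11 at 6.08.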

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

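The tests of sort position, mixing, depth, exchanged labels and leaked reads and the counts over other splits were chosen after the results were seen. In the groups of 4, 94 sets of 4 values were searched for a library far from the others, 20 were found and 4.7 are expected by chance. Of the library measures, Lrig1 in the library labelled normal Lrig1-high S10 was far below the other 3 (log2 CPM 5.19 against 6.98 to 7.19), and the 50 genes with most counts took 30.6% of the counts without ribosomal RNA in S14. Among the list levels, in mean log2(CPM + 1), S10 stood apart from the other normal Lrig1-high libraries for stem cell genes (4.50), DNA replication (3.21), colonocyte (5.81), basement membrane (2.69), matrix remodelling (1.82), fetal and regenerative (2.56), BMP and TGF-beta (3.37), glycolysis and hypoxia (5.96), endothelial (1.15), fibroblast (0.425) and muscle, glia and neuron genes (0.44). S09 stood apart from the other normal Lrig1-low libraries for stem cell (5.84), Wnt target (3.52), Paneth (5.77), Notch (3.57) and antigen presentation genes (3.82). Antigen presentation genes were also low in the libraries numbered next to it, at 3.93 in S10, 3.03 in S11 and 3.55 in S12, against 4.55 to 5.12 in the other libraries of all groups. S01 stood apart for fatty acid oxidation (5.89) and S05 for posterior Hox genes (0.062).

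The first pattern is that Lrig1 and the sort levels went against the labels in S07, S08, S09 and S10. On 100 genes per direction taken from the 6 other normal libraries, without Lrig1 and the lists that raised the doubt, a position of 0 is the mean of Lrig1-low and 1 that of Lrig1-high. S07 and S09, labelled low, lay at 0.954 and 0.665, and S08 and S10, labelled high, at 0.141 and 0.0403, so that 4 of 4 lay on the side of the other label. An exchange of the sort labels within S07 and S08 and within S09 and S10 may account for this. The 4 were picked by genes that mark the sort, and other genes that vary with those were not kept out of the position. Defensins outside the Paneth list are an example. A position on the other side was therefore likely from the start and is not independent evidence of an exchange. In mean log2(CPM + 1), S10 was at 3.72 for Wnt targets and 2.69 for basement membrane genes. The Lrig1-low libraries S01, S05 and S13 were at 2.36 to 2.37 and 1.86 to 1.99, which an exchange alone leaves unexplained. For colonocyte (5.81) and tuft cell genes (4.21) S10 lay within their ranges. S11, labelled low and with low Lrig1, lay at 0.564. S12, labelled high, lay at 0.456 on the genes higher in Lrig1-high cells and at 1.10 on the lower ones. The position is therefore less sharp in tumors. Equal mixing of both fractions in all 4 is argued against by 3 of the 4 positions below 0.25 or above 0.75. For S09, at 0.665 and with Lrig1 at 85.5 CPM, mixing stays open. Both Lrig1 orders (2 of 2) were kept after thinning to the smallest total. CPM are already scaled to depth, so thinning was unlikely to reverse such gaps and does not decide on depth. An exchange of S09 and S10 with tumor libraries is argued against by 0 tumor libraries with Wnt targets as low as the other normal libraries. S09 at 3.52 and S10 at 3.72 were themselves above the highest of those normal libraries, S06 at 3.51. They were below the lowest tumor library, S08 at 3.87. Single wrong labels and unseen tumor cells in normal tissue stay open, and no biological explanation was tested.

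The second pattern is the 357 counts in the library labelled tumor Lrig1-low S15, which was left out of the 14 libraries compared. Its 220 counts outside ribosomal RNA and the most counted gene without a symbol had the highest log likelihood under the composition of the normal Lrig1-high library S14 (-1364.2), 354 above the best library of its own group, S03 (-1718.2). Camk2d had 56 counts in S15 and 11340 CPM in S14 against 132.5 CPM in S03. Reads leaked from the libraries sequenced beside it are a candidate explanation, and a failed library with a few reads of its own stays open for the rest.

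The difference of the sort between tissues passed camera for 15 lists, and for none with an estimated correlation. The medians of the interaction, in log2, were below 0 for stem cell (-1.77), Wnt target (-2.32), DNA replication (-0.97), Paneth (-2.37), basement membrane (-1.85), matrix remodelling (-1.62) and endothelial genes (-2.84). They were above 0 for colonocyte (0.77), goblet (0.77), tuft (1.78), fatty acid oxidation (0.21), oxidative phosphorylation (0.40), cholesterol synthesis (0.30), antigen presentation (0.52) and mitochondrial genome genes (1.66). The tuft cell median was 7.47e-06 (camera adjusted p = 0.843) and the endothelial median -2.22 (camera adjusted p = 0.0508) without the 4 libraries in doubt, a set chosen after seeing the data.

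Other splits of the libraries were counted for each number of calls, without regard to the runs of library numbers and without adjustment over the 4 comparisons and the interaction. In tumor against normal Lrig1-low cells, 1 of 35 splits, the real one itself, gave as many calls, with 46 calls against 41 in the highest other split. The share is under 0.05 for this comparison taken alone. It is the smallest share 35 splits can give, and the count was 0 without S01, so chance is not excluded. The split with 41 calls sets S01, S05 and S13 against the tumor libraries and S09, which is the real contrast with S09 moved to the tumor side, and each remaining split called 0. Where the real split called 0, each split has as many by construction and the count says nothing about chance. This holds for the normal sort, where 35 of 35 splits had as many and the split that exchanges S09 and S10 called 43, a structure of the samples that repeats the doubt about these libraries and is not independent evidence of it. It also holds for tumor against normal Lrig1-high cells, where 35 of 35 had as many and the highest, 434, exchanges S04 and S10, which points to a structure of the samples. In the tumor sort the real split and the highest of the 10 splits both called 0, and 10 splits are too few for a share under 0.05. For the interaction the real split and all of the 100 splits drawn called 0.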

How the results depend on the processing

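Leaving out S15 was chosen after the data were seen, as were the sets without 4 or 5 more libraries, while the fit with S15 was the first plan and the other settings were fixed with it. Over all settings and the 4 comparisons and the interaction, 287 counts stayed within 1.5 times and 92 moved beyond. Of the values of named genes 438 kept their side of the threshold, 133 lost the call, 4 gained it and 0 called values turned, while Lrig1 in the tumor sort, not called, was at -0.31 without S04. Of the list values, called or not, 3002 kept their side of the threshold, 266 lost the call and 182 gained it. The causes of the changes were not tested.

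Counts are given as higher and lower, in the order normal sort, tumor sort, tumor against normal in Lrig1-high and in Lrig1-low cells, and interaction. In the 14 libraries they were 0 and 0 except for 43 and 3 in Lrig1-low cells. DESeq2 gave 1 and 0, 6 and 16, 74 and 40, 545 and 161, and 1 and 4, with an overlap of tumor calls of 38 between Lrig1-high and Lrig1-low. Limma-voom with sample weights gave 2057 and 2112 in the normal sort and 1060 and 329 in Lrig1-low cells. Without the 4 libraries in doubt they were 474 and 322, 45 and 3, 12 and 0, 432 and 20, and 0 and 0, with 21 lists past the threshold in the tumor sort against 6, and overlaps of 46 sort calls and 12 tumor calls. Without those and S12 they were 1826 and 1622, 257 and 94, 19 and 0, 1523 and 584, and 3 and 0 (S04 is then the 1 tumor Lrig1-high library, assumed to vary like the other groups), with 26 lists in the tumor sort and overlaps of 319 and 14.

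In tumor against normal Lrig1-low cells the DESeq2 size factors in edgeR gave 66 higher, no filter on low counts 65 higher, at least 1 CPM in at least 4 libraries 81 and 5, only the groups compared in the fit 61 and 7, and the library S15 90 higher and 2 lower. With the library number runs as a block they were 90 and 5 in Lrig1-low and 1 and 0 in Lrig1-high cells. The labels do not tie these runs to an animal, so the block is a hint only. The lists past the threshold by camera numbered 17, 6, 13, 19 and 15 of 33 in the same order. With an estimated inter-gene correlation they numbered 0, 0, 1, 0 and 0, and by fry 0, 0, 1, 6 and 0.

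With each library left out in turn, the counts ranged from 0 to 0 in the normal sort, from 0 to 41 and 0 to 324 in the tumor sort, from 0 to 263 and 0 to 544 in Lrig1-high cells, from 0 to 226 and 0 to 59 in Lrig1-low cells, and from 0 to 7 and 0 to 150 for the interaction. Lists ranged from 14 to 19, 1 to 19, 5 to 19, 17 to 22 and 9 to 19, and overlaps from 0 to 0 and 0 to 8. The highest counts outside Lrig1-low cells came without S04. The tumor Lrig1-low group holds 3 libraries, and the test on simulated counts called 9 of 50 genes changed 2-fold there, so smaller changes can be missed at this number of libraries. For the interaction it called 11 of 50 changed 4-fold, so larger changes can be missed there.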

Other observations

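The test of the small intestine against the colon was fixed before its values were seen, and the test without defensins and the sets of left-out libraries were chosen after. Some epithelial groups were described only in part above. In tumor against normal Lrig1-high cells the enteroendocrine list had a median log2 fold change of -0.71 over 25 members (camera adjusted p = 0.00174, and adjusted p = 0.827 with an estimated correlation), with Chgb at -1.75 ± 0.63 and Chga at -1.83 ± 0.68, neither past the threshold. In the Lrig1-low fraction the same list had a median of -1.08 (camera adjusted p = 0.000209, and adjusted p = 0.396 with an estimated correlation). The genes of the mitochondrial genome had a median of 1.06 in the first of these comparisons and of -0.56 in the second.

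The third pattern is that transcripts of the upper gut were abundant in libraries labelled colon. In 14 of 14 libraries the median of the small intestine markers was above that of the colon markers, at 69.8 to 382.4 CPM against 1.44 CPM or less, as cells of the small intestine would give. Without the defensins and Lyz1 the order was the same in 14 of 14 libraries, with medians of 73.1 to 538.4 CPM. The pattern therefore does not rest on the defensins. Only Lyz1, Defa17 and Defa22 left the list, so the order could hardly have turned. The test does not decide whether the defensins share reads. Fabp6, a bile acid binding protein of the ileum, was at 91.3, 3.56 and 12.2 CPM in the tumor Lrig1-low libraries S03, S07 and S11 and at 0 to 14.9 CPM in the normal Lrig1-low libraries. A different region of the gut at dissection may account for it and was not tested, and no biological explanation was tested, since no group of the design names a region.

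Leaving out the 4 libraries in doubt was set against 99 other sets of 1 library left out per group. For the normal sort it gave 796 calls, where the median of the other sets was 0, 3 of the 100 sets, itself included, were as large and the highest, without S09, S10, S07 and S12, gave 1830. For the tumor sort it gave 48, the most of the 100 sets, with 38 in the next. For tumor against normal Lrig1-high cells it gave 12, with 11 of the 100 sets as large, itself included, and 1489 in the highest. For tumor against normal Lrig1-low cells it gave 452, with 9 of the 100 sets as large, itself included, and 1792 in the highest. For the interaction it gave 0, where 7 other sets gave a call and the highest, without S09, S10, S03 and S12, gave 521. All 14 libraries had Xist counts at 759.4 to 4085 CPM and 0 CPM of Ddx3y, Eif2s3y, Kdm5d and Uty.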
